A study of Mus musculus with 60 samples.

How the data were processed

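The series holds bulk RNA sequencing of liver and inguinal white adipose tissue from diet-induced obese mice. The 60 libraries form 12 groups of 5, in 4 tables of 15 libraries, 1 per tissue and mouse line. Per the labels, the libraries were stranded poly(A) libraries sequenced on a NovaSeq X instrument. The deposited values are FPKM, fragments scaled to transcript length and library size, computed by the authors with RSEM. The RSEM version, the aligner, the genome build and the annotation are not given in the sources used here, so genes are named by the symbols of the tables and no coordinates are given. Each table lists 54343 symbols, of which 91.1% were found in the reference list of mouse gene names.

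Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, so every fold change is on that scale and is damped for genes near the floor. A gene was tested where at least 5 of the 15 libraries of its table reached 1 FPKM. A linear model with the 3 groups of a table was fitted, with a mean-variance trend in the empirical Bayes step, and each of the 8 contrasts was set against the floxed vehicle group of the same line and tissue. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over the genes tested. The difference of the conjugate effect between the lines was tested with an interaction contrast over the 30 libraries of a tissue. Errors given with a log2 fold change are standard errors of the model, and errors given with FPKM are SD over 5 libraries.

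Before the data were examined, 45 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes the 10 largest rises and falls among called genes whose groups do not overlap and whose higher mean is at least 5 FPKM, leaving out unnamed gene models, and up to 4 called members of each list with the largest change, and Glp1r, Gipr, Wnt1 and Syn1. Where fewer than 5 genes were called, the 5 with the smallest p were taken. For genes named for the largest rises and falls, groups that do not overlap are thus a condition and no further evidence. Among all genes tested, the groups did not overlap for 4.51% to 12.3% in the contrasts with calls. Lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, were run beside it. Of the 87 list calls with the preset correlation, 2 held with the estimated one, namely the male-biased liver list in each of the knockout contrasts.

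Both contrasts of a table share its vehicle libraries, which by itself gives a correlation between their fold changes. Correlations and covariances across genes are therefore given beside the mean of 100 simulations of unchanged groups. Their noise was independent between genes and libraries, so the simulated values leave out any structure of the samples. Genes are not independent replicates, so such correlations have no p. Marker scores are the mean of log2(FPKM + 1) over a list, compared by exact permutation over the 252 assignments of 10 libraries, whose smallest two-sided p is 0.00794.

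The tables hold no counts. Depth was estimated from the low values with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Genes with a single transcript of 1500 to 6000 bases in the GENCODE reference at hand, whose build may differ from that of the authors, were used, with 200 bases taken off each length. The depth at which most values came to exactly 1 fragment, within 5%, was taken. A median of 13.9% of the liver values above 0 lay at 1 fragment, 7.89% at 2 fragments and 0.04% at 0.5 of a fragment. The adipose medians were 12.9%, 7.07% and 0.095%. The estimates depend on the assumed lengths, so they serve to compare libraries and give only an approximate total. No interval of counting error was derived from them.

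The fit was tested on simulated data with the means and spread of each table and 200 genes changed in each of the 8 contrasts. Of the genes changed 2-fold, 74.6% to 97.0% were called in the right direction, and of those changed 1.5-fold, 38.8% to 91.0%. Unchanged genes made up 3.52% to 7.43% of the calls. The simulated noise was independent between genes and libraries, so these shares leave out errors from correlated genes or from a structure of the samples.

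The alternatives were another pseudocount (0.1), no filter and a stricter filter on low values, 3 rescalings between libraries, the replicate number as a block, a fit of only the 2 groups compared, robust empirical Bayes, array weights, a 1.5-fold minimum, the series of the library numbers, and each library left out in turn. Terms for the B cell score, the pancreas score and the estimated depth, and a fit without the libraries with a B cell score above 5, were added after the data were examined. Results for a few single genes are not reported. Count models were not used, since the tables hold FPKM. Figures were drawn with matplotlib 3.10.9. Mice of the knockout lines given the conjugate are not among these samples.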

Results

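Liver and inguinal white adipose tissue were profiled in 2 lines of diet-induced obese mice. One line carried floxed Glp1r alleles and the other floxed Gipr alleles, the genes of the receptors for the gut hormones GLP-1 and GIP. In each line and tissue there were 5 libraries of floxed mice given vehicle, 5 of floxed mice given mGIPR-Ab/P1, and 5 of knockout mice given vehicle. The treatment mGIPR-Ab/P1 is a conjugate of an antibody against the GIP receptor with a GLP-1 peptide. The knockouts, written Glp1rWnt1-/- and GiprSyn-/- in the labels, are named after Wnt1 and Syn1, genes of neural tissue. The title of the series concerns the need for both receptors in the central nervous system. Knockout mice given the conjugate are not among these samples, so that need is not tested here. What can be compared is the effect of the conjugate in each floxed line and the effect of each knockout without treatment.

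The estimated depth was 31.8 to 57.3 M fragments (M, 1e6) in liver and 29.9 to 64.3 M in adipose tissue. In liver of the Glp1r line depth followed the treatment. The conjugate libraries held 34.1 ± 1.57 M fragments and the vehicle libraries 49.98 ± 2.92 M (SD, n = 5 each), with no overlap (exact permutation p = 0.00794, adjusted over 8 comparisons 0.0635). In the other 7 contrasts the depths of both groups overlapped. Cells of other tissues also left traces. A B cell score above 5 was found in 6 adipose libraries: replicate 2 of the Glp1r vehicle group, replicates 1 and 3 of the Glp1r knockout, replicate 1 of the Gipr conjugate group and replicates 1 and 5 of the Gipr knockout.

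**Figure D1:**
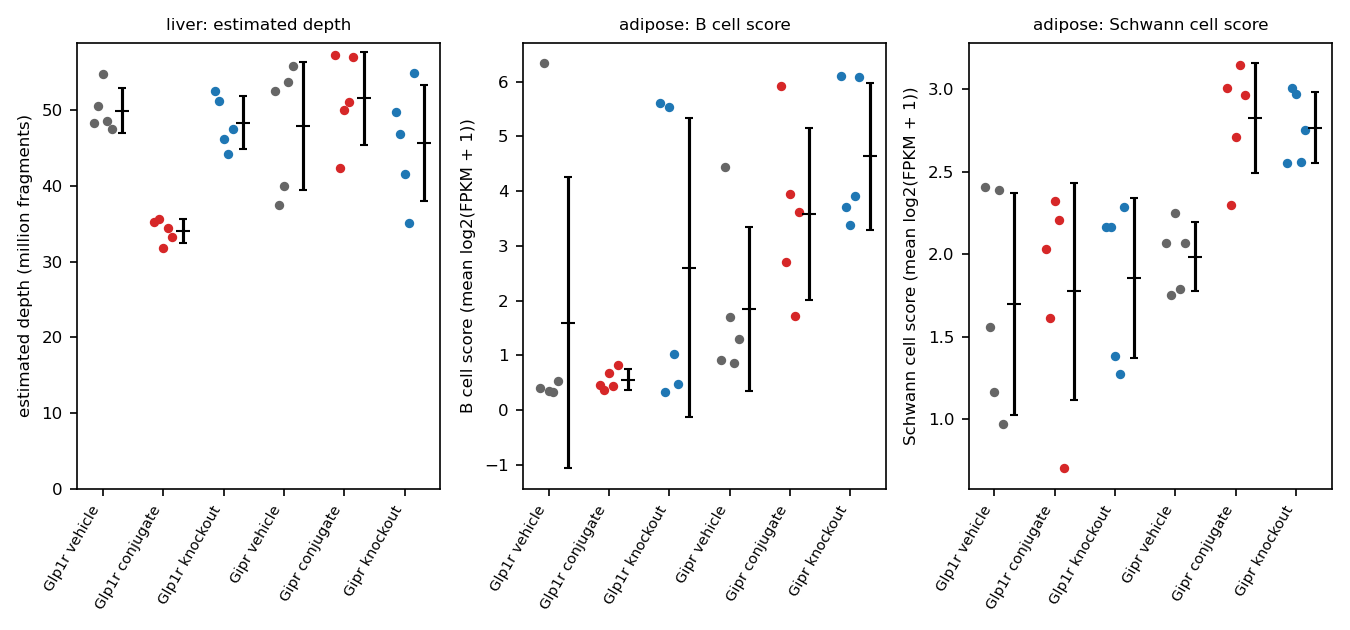
Each point is 1 library, with the mean and SD of its group of 5 beside the points; the vertical axes give the estimated depth of the liver libraries in M fragments and the B cell and Schwann cell scores of the adipose libraries as mean log2(FPKM + 1). The conjugate livers of the Glp1r line lie between 31.8 and 35.6 M fragments and their vehicle livers between 47.6 and 54.8 M.

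In liver of Glp1r floxed mice genes of lipid and sterol synthesis were lower with the conjugate. A contribution of the lower depth of these libraries cannot be told apart from the treatment. Of 22 measured genes of cholesterol synthesis and uptake, 14 fell, none rose and 8 did not pass, and 18 fell when adjusted over the list alone. Sqle, which encodes squalene epoxidase of the sterol pathway, went from 16.8 ± 6.41 to 3.51 ± 3.17 FPKM (SD, n = 5 each), a log2 fold change of -2.18 ± 0.50. Hmgcs1, an enzyme early in the same pathway, fell by 1.42 ± 0.31 and Mvd by 1.48 ± 0.30. Of 16 genes of fatty acid synthesis, 6 fell and 1 rose, with Elovl5, a fatty acid elongase, at -1.12 ± 0.25 and Acacb, an acetyl-CoA carboxylase, at -1.24 ± 0.25. Of 20 genes of triglyceride storage, 7 fell and 1 rose, among them the fatty acid transporter gene Cd36 (-1.07 ± 0.21). Apoa4, which encodes an apolipoprotein, went from 1730 ± 666 to 452 ± 226 FPKM, and Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, from 173 ± 21.4 to 84.5 ± 25.0 FPKM. Of 11 male-biased liver genes, 6 rose and none fell. Hsd3b5, a steroid dehydrogenase gene of male mouse liver, went from 1.27 ± 1.79 to 25.9 ± 17.6 FPKM and Serpina1e from 131 ± 77.3 to 750 ± 394 FPKM. For Sqle, Apoa4, Cyp8b1, Hsd3b5 and Serpina1e the 5 conjugate libraries all lay beyond the 5 vehicle libraries. Reads of Serpina1e, like those of the Gst, Mup and Cyp genes named here, may be shared with close paralogs, so the member of the family is uncertain.

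Among 10858 genes tested in that contrast, 617 were higher and 509 lower with the conjugate, of which 200 changed at least 1.5-fold. The libraries of the groups did not overlap for 994 genes, 9.15% of those tested, where chance gives 0.794%. Rescaling each library to a common sum turned the balance to 340 higher and 467 lower. The cholesterol list passed camera with an adjusted p of 3.5e-12, but adjusted p = 0.469 with an estimated correlation. The share of mitochondrial transcripts was lower with the conjugate (11.4% against 12.97%, adjusted exact p = 0.0397), as were the scores of erythrocyte markers, cholangiocyte markers and immediate early genes (differences of -0.816, -0.296 and -0.403, adjusted exact p = 0.0397 each). With the estimated depth as a term, chosen after the data were seen, no gene was called and 1260 had an unadjusted p under 0.05. The groups account for most of the variance of log2 depth (R2 = 0.914), and among the 1126 genes the log2 fold change had a median of 1.04 times its value and its standard error 3.13 times. Of these genes 1010 (89.7%) kept their sign and the rest turned. List medians moved unevenly with the term, from -0.72 to -0.89 for cholesterol, from -0.73 to -0.36 for fatty acid synthesis, from -0.46 to -2.13 for lipid-associated macrophage markers and from 0.20 to -0.19 for circadian clock genes. Leaving out vehicle replicates 2, 3, 4 or 5 gave 479, 677, 695 or 748 genes, and leaving out conjugate replicates 1 or 3 gave 574 or 728.

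In liver of Gipr floxed mice the conjugate changed many of the same kinds of genes. Of 20 genes of triglyceride storage, 5 fell and none rose, and 10 fell when adjusted over the list alone. Cidec, which encodes a lipid droplet protein, went from 36.8 ± 27.9 to 4.28 ± 2.45 FPKM (SD, n = 5 each), Mogat1, an acyltransferase gene of glyceride synthesis, had a log2 fold change of -1.78 ± 0.25, and Cd36 one of -1.33 ± 0.22. Apoa4 went from 798 ± 432 to 134 ± 65.0 FPKM and Cyp8b1 from 180 ± 71.7 to 48.8 ± 11.8 FPKM. Of 12 male-biased genes, 5 rose and none fell, with Hsd3b5 going from 4.05 ± 4.56 to 90.1 ± 43.8 FPKM and Serpina1e at 3.58 ± 0.52. Egfr, the epidermal growth factor receptor gene, rose by 1.64 ± 0.22. Of 15 xenobiotic metabolism genes, 7 fell and 1 rose, with the glutathione transferase gene Gstm3 at -2.06 ± 0.41. Of 22 cholesterol genes, 1 fell: Hmgcs1, at -1.17 ± 0.24. For Cidec, Apoa4, Cyp8b1 and Hsd3b5 all 5 conjugate libraries lay beyond the 5 vehicle libraries.

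Of 11201 genes tested, 131 were higher and 355 lower, and 228 changed at least 1.5-fold. The triglyceride storage list passed camera (adjusted p = 1.9e-06; adjusted p = 0.320 with an estimated correlation), as did the male-biased list (adjusted p = 2.6e-06; adjusted p = 0.320 with an estimated correlation). A fit of only the 2 groups compared called 149 genes, rescaling to a common sum 299 and the depth term 268. Pancreas transcripts were found in most of these libraries, with scores of 3.45, 8.26, 0.120, 4.88 and 8.27 in the vehicle and 0.0534, 7.55, 4.53, 9.18 and 2.38 in the conjugate livers, and with that score as a term 645 genes were called. The erythrocyte score differed by -0.900 (exact p = 0.0238, adjusted 0.476), and 3 of 5 erythrocyte markers fell. Without vehicle replicates 2, 3 or 4 the count was 221, 163 or 165, without conjugate replicates 2, 3 or 4 it was 197, 233 or 159, and without conjugate replicate 5 it was 1039.

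The effects of the conjugate in liver ran alike in both lines, which share no library. Across 10640 genes the fold changes correlated with r = 0.754. Genes higher in both lines numbered 56, where 7.26 are expected from the counts alone, genes lower in both 160 against 16.4, and no gene was called in opposite directions. Of the 76 genes named in either line, 74 had the same sign in both and 31 were called in both. No gene of 11549 was called in limma's test of the difference between the lines (660 had an unadjusted p under 0.05, smallest adjusted p = 0.791). The cholesterol list fell further in the Glp1r line, by a median difference of 0.57 on the log2 scale (camera adjusted p = 2.5e-13; adjusted p = 0.958 with an estimated correlation). That line is also the one whose liver libraries differ in depth between the treatments.

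**Figure D2:**
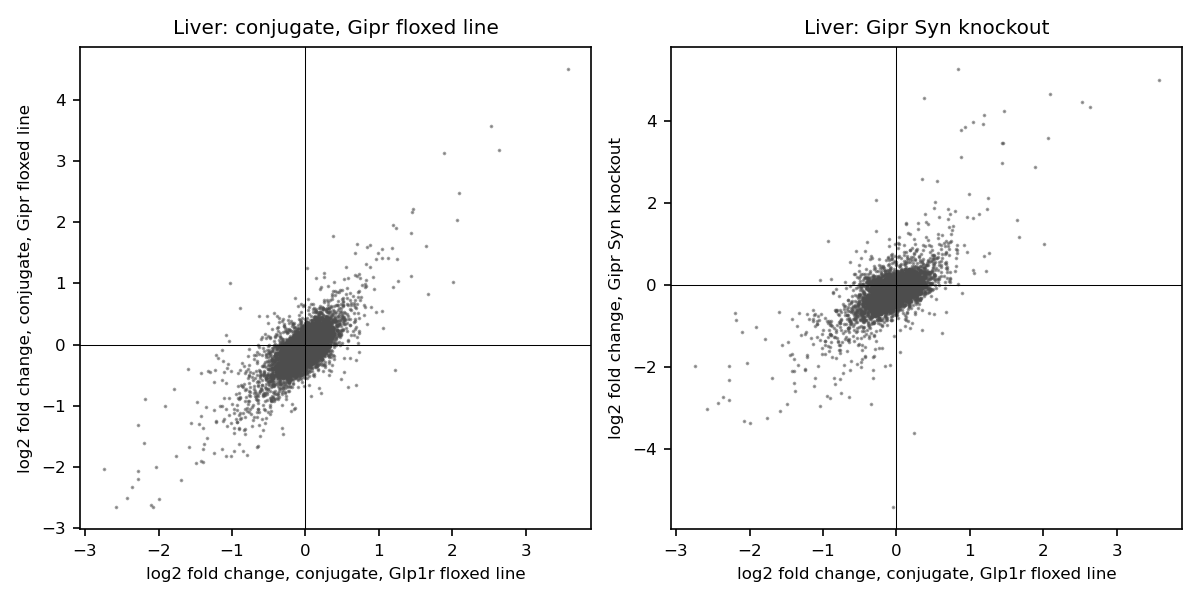
Each point is 1 of 10640 genes; the horizontal axis of both panels is the log2 fold change of the conjugate in liver of the Glp1r floxed line, and the vertical axes are the log2 fold changes of the conjugate in the Gipr floxed line and of the Gipr Syn knockout. The correlations across genes are 0.754 and 0.662, and no library is shared between the axes.

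In liver of untreated Glp1rWnt1-/- mice no single gene passed the threshold, while the male-biased list did as a group. Of its 11 measured genes, 9 passed when adjusted over the list alone, all of them higher, with a median log2 fold change of 1.02 (camera adjusted p = 3.2e-23; adjusted p = 0.0264 with an estimated correlation). Serpina1e was at 863 ± 394 FPKM against 131 ± 77.3 (SD, n = 5 each; adjusted p = 0.081) and Hsd3b5, chosen after its values were seen, at 28.0 ± 21.2 against 1.27 ± 1.79 (adjusted p = 0.14). Cholesterol genes had a median of -0.56, with 4 of 22 passing adjusted over the list alone (camera adjusted p = 5.5e-10; adjusted p = 0.472 with an estimated correlation). Of 9 heat shock genes, 5 passed adjusted over the list alone, all higher (camera adjusted p = 1.4e-07; adjusted p = 0.299 with an estimated correlation). The genes with the smallest p were Ppif, Cyp4a12b, Hao2, Serpina1e and Mup13. In limma 1048 genes had an unadjusted p under 0.05, array weights called 52 genes, and without knockout replicate 5 the count was 81.

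In liver of untreated GiprSyn-/- mice genes of lipid synthesis and of fatty acid oxidation were both lower, and male-biased genes were higher. Of 27 genes of fatty acid oxidation and ketogenesis, 21 fell and none rose. Cyp4a14, a fatty acid omega-hydroxylase gene, went from 209 ± 53.5 to 4.77 ± 4.24 FPKM (SD, n = 5 each), a log2 fold change of -5.42 ± 0.43, and Acot3, an acyl-CoA thioesterase gene, had one of -3.60 ± 0.40. Scd1, the stearoyl-CoA desaturase gene, went from 1920 ± 1219 to 219 ± 80.01 FPKM, and 9 of 17 fatty acid synthesis genes fell with none rising. Of 20 triglyceride storage genes, 14 fell, including Cidec, from 36.8 ± 27.9 to 2.11 ± 0.909 FPKM. Of 22 cholesterol genes, 10 fell. Of 12 male-biased genes, 11 rose, with Selenbp2, a selenium-binding protein gene, going from 12.5 ± 2.17 to 526 ± 158 FPKM and Hsd3b5 from 4.05 ± 4.56 to 113 ± 42.0 FPKM. Of 5 female-biased genes, 3 fell, with the steroid hydroxylase gene Cyp17a1 at -3.08 ± 0.31. Cps1, the first enzyme of the urea cycle, rose by 0.86 ± 0.17 and Cyp1a2, a cytochrome gene of the zone around the central vein, by 1.86 ± 0.21. For Cyp4a14, Scd1, Cidec, Selenbp2 and Hsd3b5 all 5 knockout libraries lay beyond the 5 vehicle libraries.

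Of 11201 genes tested, 161 were higher and 999 lower in that contrast, and 543 changed at least 1.5-fold. Over all genes the median log2 fold change was -0.11, against 0.01 with median-of-ratios scaling and -0.21 with rescaling to a common sum. Median-of-ratios scaling called 270 higher and 467 lower, quantile normalization 289 and 432, and rescaling to a common sum 136 and 1840. The male-biased list passed camera with an adjusted p of 2.8e-29 and kept its call with an estimated correlation (adjusted p = 0.00498). The oxidation list had a camera adjusted p of 7.4e-17, and adjusted p = 0.106 with an estimated correlation. Leaving out knockout replicate 2, or vehicle replicates 3 or 4, gave 694, 714 or 765 genes. The pancreas score averaged 1.66 in the knockout and 4.997 in the vehicle livers (exact p = 0.119), and with it as a term 1399 genes were called, 1027 of them shared. Scores of erythrocyte, cholangiocyte and lipid-associated macrophage markers were lower by differences of -0.575, -0.314 and -0.664 (exact p = 0.00794, 0.0159 and 0.0317, adjusted 0.127 each). The heat shock score differed by -0.201 and the sum of FPKM by 46690 (exact p = 0.0317, adjusted 0.127 each), and the immediate early score by -0.349 (exact p = 0.0397, adjusted 0.132). Knockout replicate 5 stood apart with an MHC class II score of 6.71, where the other 4 knockout livers lay between 3.19 and 3.56.

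The fold changes of the knockout and of the conjugate ran along each other in liver of the Gipr line (r = 0.685 over 11201 genes). Both share the vehicle libraries, and unchanged groups gave a simulated mean r of 0.502. The covariance was 0.0777 against 0.0233 simulated. With the controls split between the contrasts, so that no vehicle library was shared, r averaged 0.467. The simulated r was made for shared libraries and is no reference for that value. Against the conjugate effect of the Glp1r line, which shares no library, the Syn knockout correlated with r = 0.662. The Wnt1 knockout, again with no library shared, correlated with the conjugate effect of the Gipr line with r = 0.518 and with the Syn knockout with r = 0.726. In the Glp1r line r was 0.613 against 0.500 simulated, with a covariance of 0.0296 against 0.00801.

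**Figure D3:**
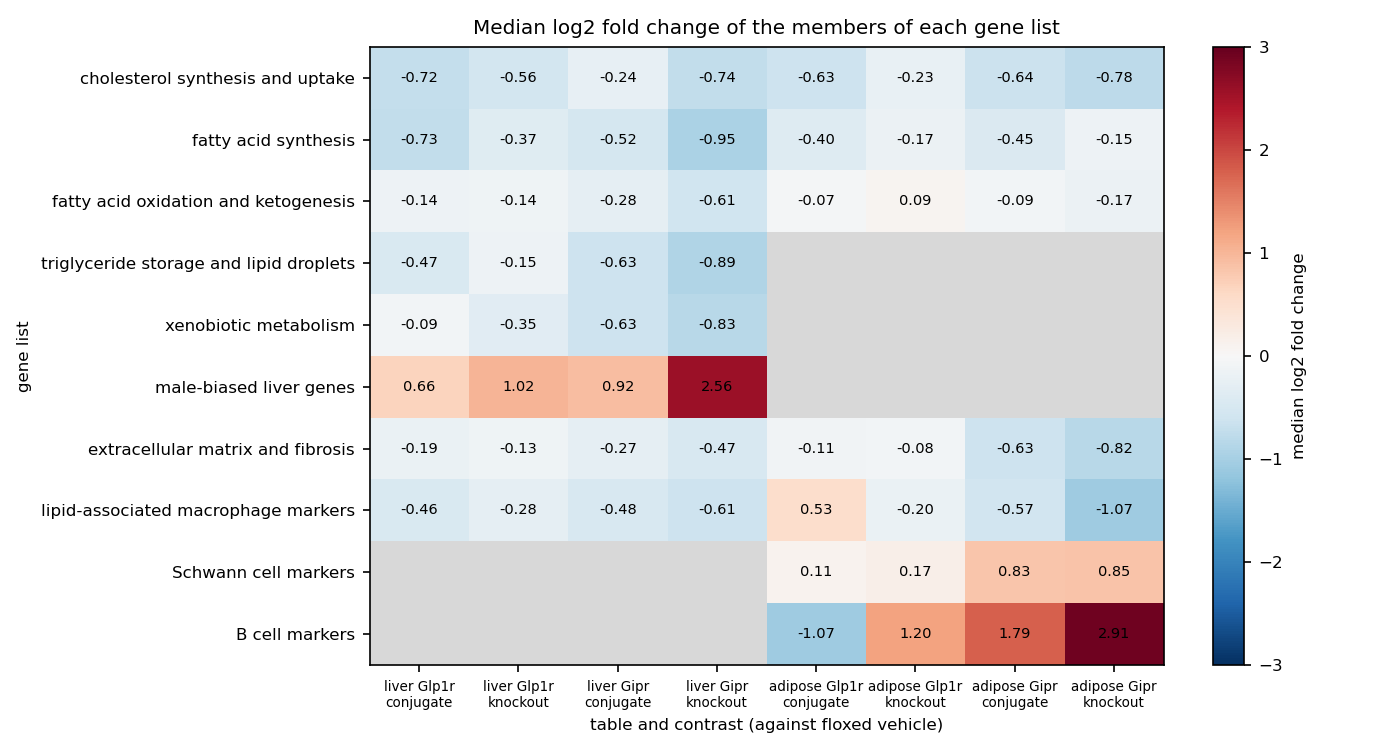
Each cell gives the median log2 fold change of the measured members of a gene list (vertical axis) in 1 of the 8 contrasts against floxed vehicle (horizontal axis); grey marks lists not tested in that tissue. The cholesterol list is below 0 in all 8 contrasts, from -0.78 to -0.23.

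In inguinal adipose tissue of Glp1r floxed mice the conjugate raised Gpx3 and Pck1 and lowered genes of sterol and fatty acid synthesis. Gpx3, a secreted glutathione peroxidase gene, went from 77.6 ± 13.98 to 261 ± 54.0 FPKM (SD, n = 5 each) and Pck1, a gene of glyceroneogenesis, from 246 ± 58.3 to 628 ± 158 FPKM. Angptl8, an insulin-responsive regulator of lipoprotein lipase, went from 28.6 ± 10.3 to 7.34 ± 3.34 FPKM. For these 3 genes all 5 conjugate libraries lay beyond the 5 vehicle libraries. Of 21 cholesterol genes, 10 fell and none rose, with Lss, the lanosterol synthase gene, at -1.06 ± 0.16 and Cyp51, the sterol demethylase gene that follows it, going from 14.7 ± 2.90 to 6.78 ± 1.14 FPKM. Of 17 fatty acid synthesis genes, 6 fell and none rose, among them the acetyl-CoA synthetase gene Acss2 (-1.27 ± 0.22). Of 13 thermogenic genes, 3 fell, with Elovl3 at -1.56 ± 0.24 and the glycerol kinase gene Gk at -1.03 ± 0.14.

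Of 12686 genes tested, 293 were higher and 137 lower, and 213 changed at least 1.5-fold. The cholesterol list had a camera adjusted p of 4.5e-18, and adjusted p = 0.106 with an estimated correlation. The count rested on single libraries. It was 1087 without vehicle replicate 2, which is rich in B cell transcripts, 690 and 742 without conjugate replicates 2 and 5, 96, 115 and 94 without vehicle replicates 3, 4 and 5, and 87, 76 and 95 without conjugate replicates 1, 3 and 4. Without the libraries with a B cell score above 5, 2610 genes were called, 427 of the 430 among them, while a fit of only the 2 groups compared called 58 and the depth term 72.

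In adipose tissue of Gipr floxed mice Gpx3 and Pck1 rose too, some matrix and cell cycle genes fell and Schwann cell markers rose. Gpx3 went from 81.4 ± 10.8 to 388 ± 97.7 FPKM (SD, n = 5 each) and Pck1 from 266 ± 118 to 661 ± 206 FPKM. Slc2a4, the insulin-responsive glucose transporter gene, rose by 0.72 ± 0.15. Tph2, a tryptophan hydroxylase gene, went from 35.7 ± 11.1 to 3.67 ± 3.71 FPKM. For Gpx3 and Tph2 all 5 conjugate libraries lay beyond the 5 vehicle libraries, while those of Pck1 overlapped. Of 21 cholesterol genes 10 fell and none rose, and of 17 fatty acid synthesis genes 8 fell and 1 rose, with Fasn, the fatty acid synthase gene, at -1.51 ± 0.30. Of 22 matrix genes 7 fell and 2 rose, including the basement membrane collagen gene Col4a1 (-1.15 ± 0.24), and of 17 cell cycle genes 5 fell (10 adjusted over the list alone), including Cdk1 (-1.17 ± 0.18). All 7 measured Schwann cell markers rose, with a median of 0.83.

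Of 13604 genes tested, 579 were higher and 376 lower, and 521 changed at least 1.5-fold. Conjugate replicate 5 and knockout replicate 5 carry library numbers of a higher series, which holds no vehicle library in this tissue. Without them 569 genes were called. Median-of-ratios scaling gave 274 higher and 491 lower, and quantile normalization 186 and 448. The lists passed camera but not with an estimated correlation, with adjusted p = 0.150 for cholesterol, adjusted p = 0.336 for matrix and for cell cycle genes and adjusted p = 0.228 for Schwann cell markers. The mitochondrial share was lower with the conjugate (7.89% against 10.5%), as was the share of the 10 most abundant genes (a difference of -2.07 points), while the immediate early score was higher by 0.341 (adjusted exact p = 0.0417 each). The B cell list had a median of 1.79. The count was 437, 506, 479 or 467 without vehicle replicates 1, 2, 4 or 5, and 528, 528 or 418 without conjugate replicates 1, 4 or 5. Without the library with a B cell score above 5 among the conjugate group and those of the knockout group, the count was 928, with 745 shared. The conjugate libraries kept had scores of 2.71, 3.95, 1.71 and 3.61, against 0.911, 4.44, 1.71, 0.867 and 1.30 in the vehicle libraries. That fit therefore does not remove the difference in B cell content. With the B cell score as a term 850 genes were called, 572 of the 955 called before among them.

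Across 12541 genes the conjugate effects of the 2 lines in adipose tissue correlated with r = 0.429, and with r = 0.692 without vehicle replicate 2 of the Glp1r line. Of 30 splits within groups of the Glp1r line, 4 gave a correlation as large in size with the conjugate effect of the Gipr line, up to 0.492. Genes higher in both numbered 128, against 12.3 expected, genes lower in both 88 against 3.81, and none went in opposite directions. Of 75 named genes measured in both lines, 71 had the same sign and 30 were called in both. In the test of the difference limma called none of 14156 genes (554 had an unadjusted p under 0.05, smallest adjusted p = 0.887), and array weights called 86.

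In adipose tissue of untreated Glp1rWnt1-/- mice no gene passed the threshold. The smallest p values belonged to Ahsa2, Gm48216, Cxcl10, Pck1 and Col12a1. Pck1 was at 480 ± 104 FPKM against 246 ± 58.3 (SD, n = 5 each), a log2 fold change of 0.97 ± 0.21 (adjusted p = 0.98). Cholesterol genes had a median of -0.23 (camera adjusted p = 2.3e-11; adjusted p = 0.426 with an estimated correlation). In limma 593 genes had an unadjusted p under 0.05 and array weights called 732. Knockout replicates 1 and 3 and vehicle replicate 2 had B cell scores of 5.60, 5.54 and 6.34, and without them the count stayed at 0.

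In adipose tissue of untreated GiprSyn-/- mice genes of lipid-associated macrophages, matrix and sterol synthesis were lower, and B cell markers, Schwann cell markers and Adrb3 were higher. Of 13 lipid-associated macrophage markers, 8 fell and none rose, with Trem2, a lipid receptor gene of these cells, going from 23.7 ± 9.29 to 4.02 ± 2.39 FPKM (SD, n = 5 each) and the elastase gene Mmp12 at -3.16 ± 0.62. Of 22 matrix genes 12 fell and none rose, with the basement membrane collagen gene Col4a2 at -1.42 ± 0.26. Of 8 mural cell markers 3 fell (4 adjusted over the list alone; adjusted p = 0.305 with an estimated correlation) and of 10 endothelial markers 1 fell (5 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). The scores of both fell by 0.449 and fell by 0.411 (exact p = 0.0159 and 0.0238, adjusted 0.0833 each). Of 21 cholesterol genes 12 fell and 1 rose. Lep, the leptin gene, went from 1463 ± 172 to 519 ± 278 FPKM, while Adrb3, the adipocyte beta-3 adrenergic receptor gene, went from 11.8 ± 5.42 to 78.8 ± 37.8 FPKM and Cfd, the adipsin gene, rose by 2.89 ± 0.59. Tph2 went from 35.7 ± 11.1 to 3.42 ± 3.39 FPKM. For Trem2, Lep, Adrb3 and Tph2 all 5 knockout libraries lay beyond the 5 vehicle libraries. Of 10 B cell markers 7 rose, and the immunoglobulin gene Igkc was at 3.48 ± 0.75. Of 7 Schwann cell markers 6 rose.

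Of 13604 genes tested, 899 were higher and 771 lower in that contrast, and 890 changed at least 1.5-fold. Without the libraries of the higher number series, which holds no vehicle library in this tissue, 985 genes were called. Median-of-ratios scaling called 588 higher and 1014 lower, and quantile normalization 462 and 877. With the B cell score as a term 237 genes were called, 191 of them shared, and without the libraries with a score above 5 the count was 755, with 651 shared. With an estimated correlation the list calls were lost, with adjusted p = 0.234 for the macrophage, matrix and cholesterol lists, adjusted p = 0.587 for B cell and adjusted p = 0.268 for Schwann cell markers. The count was 693, 1055, 928 or 867 without vehicle replicates 1, 3, 4 or 5 and 937 or 976 without knockout replicates 1 or 5.

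The knockout and conjugate effects in adipose tissue of the Gipr line correlated with r = 0.822 over 13604 genes. Unchanged groups against the same vehicle libraries gave 0.502 on average, and the covariance was 0.147 against 0.0275 simulated. With split controls, for which the simulated r is no reference, r averaged 0.669. The B cell score averaged 3.58 in the conjugate and 4.64 in the knockout group, against 1.85 with vehicle (exact p = 0.111 and 0.0317, adjusted 0.259 and 0.0833). A higher lymph node content of both groups could thus add to r, and neither the simulation nor the split controls remove it. Against the conjugate effect of the Glp1r line, with no library shared, r was 0.162, and 18 of 30 within-group splits of the Glp1r line and 20 of 30 of the Gipr line were as large. The other pairs without a shared library had higher values. The Wnt1 knockout correlated with the conjugate effect of the Gipr line with r = 0.506 (0 and 1 of 30 such splits as large) and with the Syn knockout with r = 0.520 (12 and 0 of 30). In the Glp1r line r was 0.309, with 0.500 simulated for shared libraries, and -0.101 with split controls, for which the simulated r is no reference. It rested on single libraries, with 0.577 without vehicle replicate 2, which is rich in B cell transcripts, and 0.494, 0.163, 0.505 and 0.204 without knockout replicates 1, 2, 3 and 4.

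**Figure D4:**
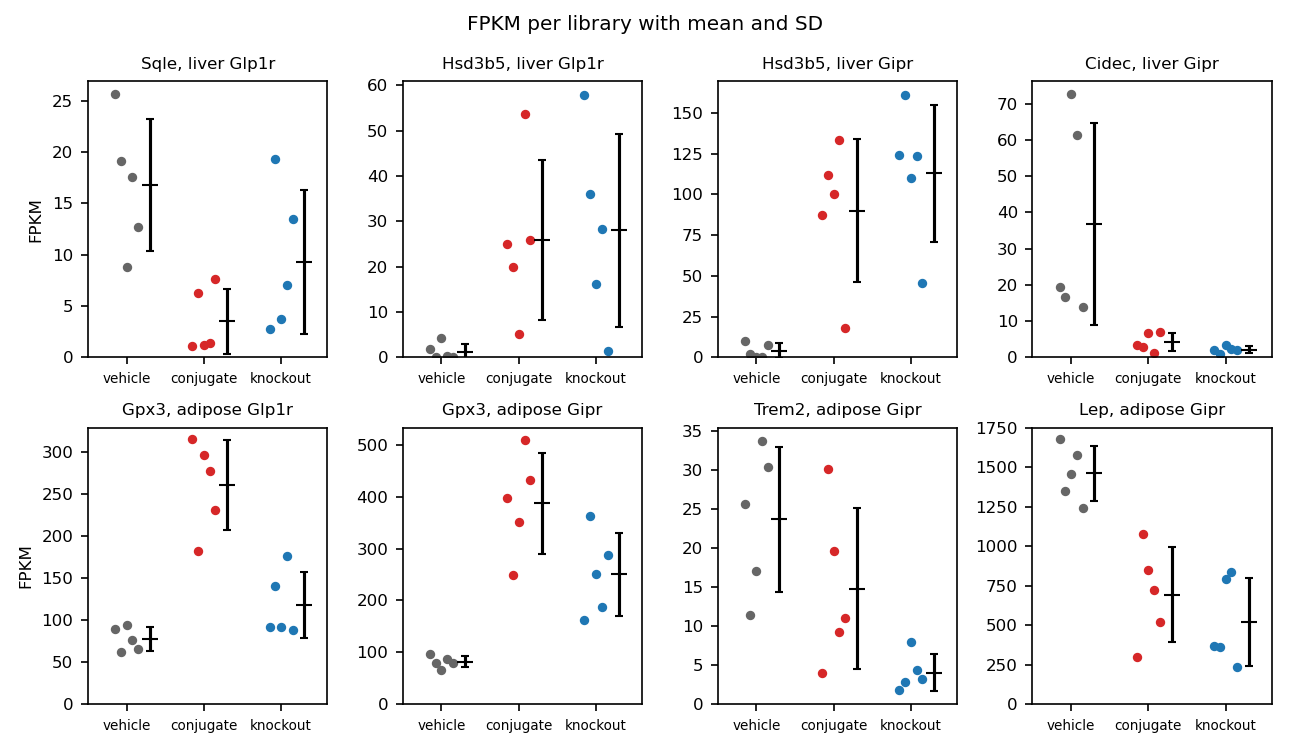
FPKM (vertical axes) of 8 gene and table combinations in the floxed vehicle, floxed conjugate and knockout vehicle groups (horizontal axes); each point is 1 library, with the mean and SD of 5 beside it. Gpx3 is above all vehicle libraries in all conjugate libraries of both lines, and Lep has a mean of 1463 FPKM in vehicle and 519 FPKM in knockout adipose tissue of the Gipr line.

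The targeted genes were near the floor in most groups. Glp1r, Wnt1 and Syn1 had group means of at most 0.448 FPKM in every group of both tissues, and Gipr was at most 0.0048 FPKM on average in liver. In adipose tissue Gipr was at 6.15 ± 1.12 FPKM in vehicle and 4.002 ± 1.11 FPKM in GiprSyn-/- mice (SD, n = 5 each; log2 fold change -0.53 ± 0.18, adjusted p = 0.0646). The lowest knockout values, 3.20 and 2.57 FPKM, were those of replicates 1 and 5, whose B cell scores lay above 5. The other knockout libraries had 4.44, 5.37 and 4.43 FPKM, and the vehicle libraries 5.02 to 7.46. Vehicle adipose tissue of the Glp1r line had 3.42 ± 1.12 FPKM. Gipr was the only targeted gene that reached the filter, and with the replicate numbers as a block 1 call of a targeted gene was made. Deletion in the nervous system cannot be read from these tissues.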

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

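The tests of shared vehicle libraries, of dilution by lymph node RNA and of depth acting on all genes, and the fits with a term for depth or the B cell score or without the libraries rich in B cell transcripts, were chosen only after the result was seen. For 273 combinations of a group of 5 libraries and a measure, 1 library far from the other 4 was sought. Of these 40 passed a gap of 0.71 of the range, where chance gives about 1 in 20 for normal values. The combinations depend on each other, since 1 library can stand apart in several measures, so the excess is not tested. A further 14 gene lists differed between the lines in their response to the conjugate by camera with its preset correlation, none of them with an estimated correlation and none with a member called.

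In liver of the Glp1r line 1126 genes differ between conjugate and vehicle libraries whose estimated depth also differs. With depth as a term Sqle went from -2.18 ± 0.50 to -2.58 ± 1.61 and Cyp8b1 from -1.08 ± 0.24 to -2.20 ± 0.70. Apoa4 went from -2.00 ± 0.40 to -4.14 ± 1.14, Hsd3b5 from 3.57 ± 0.77 to 7.98 ± 2.11 and Serpina1e from 2.53 ± 0.47 to 3.75 ± 1.48. For these 5 genes the calls ended because the standard errors grew, while the estimates grew in size as well. Of all 1126 genes 1010 kept their sign, and estimates moved there too. Depth as the whole cause is argued against by the correlation with the conjugate effect of the Gipr line (0.754, where within-group splits reached 0.468). Depth acting on the cholesterol score is argued against by its slope on log2 depth in the other 5 liver groups (-0.262 ± 0.418 SE, where 1.58 was needed). The share called was 15.8% among genes of at least 10 FPKM and 7.20% below, with 632 of the 1126 genes at or above that limit. Genes with few fragments were thus not the only ones called. The scale damps changes near the floor, so the 2 shares do not decide on counting error. A partial contribution of depth, or a difference in the handling of that group, cannot be told apart from the treatment, since the depths of both groups do not overlap.

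In liver the fold changes of the Gipr Syn knockout run along those of the conjugate. Shared vehicle libraries as the whole cause are argued against by r = 0.662 with the conjugate effect of the Glp1r line, where no library is shared and within-group splits reached 0.527. An axis along which mice of 1 group also differ gave 0 of 30 such splits as large. An effect of the knockout on body weight or intake that acts on liver as the conjugate does stays open as a hypothesis, and neither is given in the sources used here.

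In adipose tissue of the Gipr Syn knockout B cell genes are higher, and macrophage, matrix and sterol genes lower. Lymph node tissue in some samples may be the source of the B cell genes. In 6 of the 6 libraries with a B cell score above 5, the lymph node stroma score was higher than in every library of the same table without such a B cell score. For the genes that are lower, even dilution of all adipose transcripts by lymph node RNA is argued against by the adipocyte list. Its median was 0.0468, while Schwann cell markers had 0.85. The endothelial and mural cell scores differed by -0.411 and -0.449, so a partial contribution of dilution stays open. Without the libraries rich in B cell transcripts 96.9% of the 32 called members kept at least 0.7 of their log2 fold change, and 21 were still called. The knockout libraries kept had B cell scores of 3.71, 3.38 and 3.91, against 0.911, 4.44, 1.71, 0.867 and 1.30 in the vehicle libraries. That fit therefore cannot exclude lymph node content. With the B cell score as a term 237 genes were called in this contrast, 191 of them among the 1670 called before. An effect of the knockout on these genes stays open as a hypothesis.

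The libraries of each contrast were also split in 100 ways, the real one included. In liver 1 split, the real one, reached the 1126 genes of the Glp1r conjugate contrast (highest other 1). The same held for the 486 of the Gipr conjugate contrast (highest other 446) and the 1160 of the Gipr knockout (highest other 314). With 100 splits the smallest possible share is 1 in 100 for each contrast, and several contrasts were tested, so chance is not excluded. Other splits of the Gipr livers also called many genes, so a structure of the samples other than the groups stays open there. In adipose tissue 1 split reached the 955 genes of the Gipr conjugate contrast (highest other 0), and 2 splits each reached the 430 of the Glp1r conjugate contrast and the 1670 of the Gipr knockout. Their highest other splits called 1639 and 2041 genes, so a structure of the samples other than the groups is present. For the Glp1r knockouts and the differences between the lines, with 0 genes called, all 100 splits reach that count by construction, so the comparison decides nothing there. Other splits called up to 546 genes in liver and 3363 in adipose tissue for the knockouts, which points to a structure of the samples, and up to 125 and 1 for the differences. At an unadjusted p under 0.05 limma gave 1048 and 593 genes for these knockouts and 660 and 554 for the differences.

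In adipose tissue replicate 2 of the Glp1r vehicle group lay apart in B cell (6.34), T cell (5.61), MHC class II (8.28) and neutrophil (2.23) scores and in mitochondrial share (8.63%). In the same group replicate 3 had the highest sum of FPKM (527930), replicate 4 a skeletal muscle score of 5.10 and replicate 1 a hepatocyte score of 5.82. In the Glp1r conjugate group replicate 5 had macrophage and lipid-associated macrophage scores of 7.49 and 8.10 and a mammary epithelium score of 0.561, and replicate 4 a skeletal muscle score of 1.42. In the Wnt1 knockout replicate 2 had a macrophage score of 4.62 and a skeletal muscle score of 4.68. In the Gipr vehicle group replicate 2 had T and B cell scores of 4.08 and 4.44, and replicate 3 had Pck1 at 465.6 FPKM. In the Gipr conjugate group replicate 5 had an estimated depth of 56.7 M fragments, replicate 2 a macrophage score of 6.42 and replicate 1 an endothelial score of 5.24, and in the Syn knockout replicate 5 had 64.3 M.

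In liver replicate 5 of the Syn knockout lay apart in macrophage (5.82), lipid-associated macrophage (2.27), Kupffer cell (5.73), MHC class II (6.71), T cell (1.97), B cell (0.968), neutrophil (0.833) and endothelial (3.002) scores. Replicate 1 of that group had a pancreas score of 7.83, where the others of that group had at most 0.146 and 4 of 5 vehicle and 4 of 5 conjugate livers of that line had 2.38 to 9.18, and replicate 2 had Selenbp2 at 798 FPKM. In the Gipr conjugate group replicate 3 had lipid-associated macrophage and neutrophil scores of 2.77 and 0.940 and Selenbp2 at 178 FPKM, and replicate 1 an endothelial score of 2.37. In the Gipr vehicle group replicate 5 had Cyp4a14 at 303 FPKM. In the Glp1r line vehicle replicate 5 had a cholangiocyte score of 1.49, conjugate replicate 2 a mitochondrial share of 10.5%, knockout replicate 5 a neutrophil score of 1.15 and knockout replicate 1 had Cyp8b1 at 88.9 FPKM.

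The conjugate effect in the Gipr line minus that in the Glp1r line passed camera for 5 lists in liver, with median differences of 0.57 for cholesterol synthesis, 0.22 for the unfolded protein response, 0.13 for immediate early genes, 0.24 for macrophage and 0.49 for Kupffer cell markers. In adipose tissue it passed for 9 lists, with -0.48 for matrix, -0.95 for lipid-associated macrophage, 0.80 for MHC class II, 1.66 for T cell, 2.82 for B cell, -0.44 for endothelial, -0.51 for mural cell, 2.34 for skeletal muscle and 0.76 for Schwann cell lists. None passed with an estimated correlation, where adjusted p was 0.352 to 0.958.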

How the results depend on the processing

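The fits with a term for depth, B cell or pancreas score and those without the libraries rich in B cell transcripts were chosen only after the result was seen. No called named gene changed sign with the other pseudocount, the filters, the 3 rescalings or the replicate block, or when 1 library was left out, and the other alternatives were not run for named genes, apart from the depth term for some. The balance of genes higher and lower turned with scaling for the Glp1r conjugate in liver (340 and 467 with rescaling to a common sum) and, in adipose tissue of the Gipr line, for the conjugate (274 and 491 with median-of-ratios scaling) and the knockout (588 and 1014). Apart from leaving out a library, the correlation of the conjugate effects of both lines was 0.683 to 0.789 in liver and 0.222 to 0.687 in adipose tissue. Where a count moved, the cause was not tested, except that a minimum fold lowers counts by construction.

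Without a filter on low values 617 genes were called for the conjugate in liver of the Glp1r line, 146 in adipose tissue of that line, 250 in liver of the Gipr line and 1 for the adipose difference. With a mean of at least 5 FPKM it was 609 and 982 for conjugate and knockout in adipose tissue of the Gipr line. With a 1.5-fold minimum the 6 contrasts with calls had 200, 213, 228, 543, 521 and 890. Rescaling to a common sum gave 299 for the conjugate and 1976 for the knockout in liver of the Gipr line. Median-of-ratios scaling gave 2 genes for the Glp1r knockout in liver, 240 for the Glp1r conjugate in adipose tissue and 737 for the Gipr knockout in liver, and quantile normalization 2, 130, 721 and, for the Gipr conjugate in adipose tissue, 634.

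A fit of only the 2 groups compared called 58 genes for the Glp1r conjugate in adipose tissue and 149 for the Gipr conjugate in liver. Array weights called 52 and 732 genes for the Glp1r knockouts in liver and adipose tissue, 5556 for the Glp1r conjugate in adipose tissue, 1333 and 3333 for conjugate and knockout in liver of the Gipr line, 3618 and 3723 in its adipose tissue and 86 for the adipose difference. Without the libraries of the higher number series 569 and 985 were called in adipose tissue of the Gipr line, where that series holds no vehicle library. Depth as a term gave 0, 72 and 268 for the conjugate in liver and adipose tissue of the Glp1r line and liver of the Gipr line. The B cell score as a term, and leaving out the libraries rich in B cell transcripts, gave 2683 and 2610 for the Glp1r conjugate and 237 and 755 for the Gipr knockout in adipose tissue. Of the 87 list calls 2 held with an estimated correlation, while fry called 42 lists, losing 49 of the 87 and adding 4.

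In each contrast 1 to 3 of 5 libraries best matched their own replicate number, where chance gives 1 of 5. A pairing of the samples by replicate number is thus neither shown nor excluded. With them as a block 83 genes were called for the Glp1r conjugate in adipose tissue and 1 targeted gene was called where none was before.

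Leaving out 1 library at a time gave 479 to 1395 genes for the Glp1r conjugate in liver (479, 677, 695 and 748 without vehicle 2, 3, 4 and 5, 574 and 728 without conjugate 1 and 3) and 76 to 1087 in adipose tissue (1087, 96, 115 and 94 without vehicle 2 to 5, 87, 690, 76, 95 and 742 without conjugate 1 to 5). It gave 159 to 1039 for the Gipr conjugate in liver (221, 163 and 165 without vehicle 2, 3 and 4, 197, 233, 159 and 1039 without conjugate 2 to 5) and 418 to 1223 in adipose tissue (437, 506, 479 and 467 without vehicle 1, 2, 4 and 5, 528, 528 and 418 without conjugate 1, 4 and 5). For the Gipr knockout it gave 694 to 1622 in liver (694 without knockout 2, 714 and 765 without vehicle 3 and 4) and 693 to 2116 in adipose tissue (693, 1055, 928 and 867 without vehicle 1, 3, 4 and 5, 937 and 976 without knockout 1 and 5). The Glp1r knockout had 0 to 81 in liver (81 without knockout 5) and 0 in adipose tissue in all 10 fits. The liver difference stayed at 0, and the adipose difference was 0 to 1 (1 without Gipr conjugate 2 or Gipr vehicle 4). The correlations of knockout and conjugate effects were 0.511 to 0.669 and 0.163 to 0.577 in liver and adipose tissue of the Glp1r line, and 0.541 to 0.755 and 0.696 to 0.867 in the Gipr line. Those of both lines were 0.699 to 0.768 in liver and 0.321 to 0.692 in adipose tissue (0.692 without Glp1r vehicle 2).

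Of 350 calls of named genes, 111 were lost without a filter, 49 with quantile normalization, 36 with median-of-ratios scaling, 25 with the replicate numbers as a block, 24 with rescaling to a common sum, 5 with a mean of at least 5 FPKM (300 kept, the others not tested there) and 4 with the other pseudocount. Depth limits the genes with few fragments, and in simulated data 38.8% to 91.0% of 1.5-fold changes were called.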

Other observations

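Both tests of the Schwann cell markers were chosen only after the result was seen. These markers are higher in adipose tissue of the Gipr line, with a score of 2.83 under the conjugate against 1.99 with vehicle (adjusted exact p = 0.0417, higher in 5 of 5 libraries). A lower share of adipocyte RNA would raise the markers of other cell types alike, and is argued against by the endothelial list, whose median log2 fold change was -0.29 while that of the Schwann cell list was 0.83. Nerve taken along with some samples stays open: all 10 conjugate and knockout libraries lay above the highest vehicle score of 2.25, so the excess cannot be told apart from the groups. A change in nerve content or in the state of Schwann cells is a further hypothesis that was not tested.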
